A study of Rattus norvegicus with 24 samples.

How the data were processed

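Per the labels, male rats of the stroke-prone spontaneously hypertensive strain were randomized at 11 weeks of age to powdered chow with water or to chow holding 24.5% fat with 1% NaCl in the drinking water, for 2 or 8 weeks. Per the labels' protocols, whole kidneys were pulverised, RNA was extracted with Trizol and RNeasy columns, and about 5 µg of total RNA per animal was turned into biotinylated cRNA for an Affymetrix rat array. There were 4 groups of 6 animals, with 24 arrays and 1 array per animal.

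The authors deposited a table of intensity values, which per the submitters' processing notes are MAS5 signals, 1 value per probe set and array for 15923 probe sets. The version of MAS5, the scanner, the scaling target and the detection calls were not given. The deposited values were non-negative and linear, with 27 values at 0 and 0 missing. Their mean, leaving out the lowest and highest 2% of values, lay between 150.034 and 150.042 on every array, so that the arrays had been scaled to a common target. The scale and the scaling can thus be read from the values, whereas the target set by the submitters and any step before MAS5 stay unknown. No pair of arrays was a duplicate: correlations of log2 signals within groups were 0.950 to 0.981, and the closest pair of each group shared 0.578 to 0.691% identical values.

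Gene symbols came from the platform annotation and were updated through Entrez identifiers to a RefSeq gene table of the rat assembly GRCr8, which changed 0 symbols and lacked 35. Of the probe sets, 57 were array controls, 12783 had 1 symbol, 312 had several and 2771 had none. No positions are given, because the build behind the array annotation is not stated. Values were log2(signal + 7.21), where 7.21 is 0.1 times the median of the array medians, with no further normalization. Probe sets above the 40th percentile of the array, a signal of 44.48 to 54.5, in at least 6 of 24 arrays were tested, which kept 10208, of which 8656 had 1 symbol, for 7493 distinct symbols.

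Group means were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend) to all 24 arrays, which share an estimate of the spread. The 5 comparisons were diet at 2 weeks, diet at 8 weeks, their difference (the interaction), and 8 against 2 weeks on each diet. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. There were 41 gene lists, each gene represented by its probe set of highest mean log2 signal. They were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Adjusted p values of lists are from camera, and those of genes are from limma. Lists with fewer than 4 measured genes were not tested: neutrophil, adrenal medulla and nerve, urothelium, skeletal muscle, adrenal cortex, and erythroid and blood. The groups, comparisons, filter, lists, named-gene rule and first set of other settings were chosen before the data were examined.

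Named genes were, in each diet comparison, the 10 largest increases and 10 largest decreases among called genes with 1 symbol whose 6 arrays of the first group all lay beyond the median of the second group. For the interaction and for time these were the 5 largest each way, without that condition for the interaction. Up to 4 members of smallest p were named from each list described. Agt, Ace, Havcr1, Spp1, Lcn2, Clu, Col1a1, Fn1, Cd68, Nphs1, Umod, Slc12a3, Cyp4a1, Kl, Nos3, Edn1 and Hmox1 were among the genes to be named in the diet comparisons, of which others are not reported here. Nos3 lay below the filter. Scnn1b, Slc22a2, Bdh1, Fabp3, Timp3, Angptl4, RT1-CE16 and Fbln5, which moved against the direction of their list or comparison, were named after their values were seen.

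Single measures (the 3' to 5' ratios of the GAPDH and actin control probe sets, the fat index and the spike-in level) were compared between groups with exact two-sided permutation tests. The fat index is the mean standardised log2 signal of Fabp4, Cfd and Car3, and the spike-in level is the mean centred log2 signal of 18 BioB, BioC, BioD and Cre control probe sets. The first set of other settings held other pseudocounts, quantile normalization, centring of arrays on their medians, other filters, eBayes without trend or robust, array weights, the replicate number as a block, only the groups compared, each array left out in turn, camera with an estimated correlation, fry (directional and mixed), and the mean of all probe sets of a gene. Added after seeing the data were the omission of normal-diet arrays 1 and 2 at 8 weeks, and the fat index, the GAPDH ratio or the spike-in level as a covariate.

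The procedure was tested on 10208 simulated probe sets. Changes of 1 on the log2 scale were recovered in 94.0% of cases for diet at 2 weeks, 98.5% for diet at 8 weeks, 88.1% for the interaction, 94.0% for time on the normal diet and 95.5% for time on the high salt and fat diet. Changes of 0.5 were recovered in 71.6, 65.7, 44.8, 64.2 and 64.2% of cases. A list of 20 genes shifted by 0.5 was called in all 5 comparisons, and 1 unshifted list in the last. Unchanged probe sets made up 6.84, 5.88, 3.16, 2.82 and 4.42% of the probe sets called, against a nominal 5%. Other splits of the real arrays called a median of 3 to 5 lists, so the simulation cannot settle list error. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Blood pressure, histology, blood and urine measures were not available.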

Results

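Kidney RNA was measured in 24 male stroke-prone spontaneously hypertensive rats, an inbred line with genetic hypertension in which salt loading aggravates vascular and renal injury. From 11 weeks of age the animals received either ordinary powdered chow with water, or chow holding 24.5% fat with 1% NaCl in the drinking water, here called the high salt and fat diet. Salt and fat were given together, so the comparisons address their joint effect. Kidneys were collected after 2 or 8 weeks, with 6 animals for each diet and time and 1 array per animal. Changes are differences of log2(signal + 7.21) ± SE, a scale that understates the change of weakly expressed genes. Group signals are means ± SD with n = 6.

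Median signals on the 2-week normal-diet arrays were 69.0, 72.1, 71.8, 73.6, 71.9 and 70.9, and those on the 2-week high salt and fat arrays were 72.3, 68.7, 70.5, 71.3, 70.9 and 76.0. At 8 weeks the medians were 74.9, 78.7, 73.6, 73.4, 69.4 and 70.6 on the normal diet and 71.6, 71.5, 75.4, 75.0, 75.4 and 74.4 on the high salt and fat diet. The first principal component, with 19.1% of the variance, separated the diets. All 12 high salt and fat arrays had scores from 1.45 to 20.9, and all 12 normal-diet arrays had scores from -19.2 to -5.22. Normal-diet arrays 1 and 2 at 8 weeks had 1st percentile signals of 2.4 and 3.0, against 0.7 to 1.2 on the other 22 arrays. The number of arrays limits the precision of every value.

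After 2 weeks on the high salt and fat diet, transcripts of collecting duct water channels and of osmolyte accumulation were higher, and transcripts of the proximal tubule, of fatty acid oxidation and of fatty acid synthesis were lower. Camera called 11 lists with its preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.0689), and 10 of 100 splits of the arrays, the real one included, gave as many lists. Aqp2, the vasopressin-regulated water channel of the collecting duct, went from a signal of 605 ± 147 to 1331 ± 102 (1.16 ± 0.14, adjusted p = 3.76e-06). Akr1b1, aldose reductase, which makes sorbitol, went from 151 ± 12.6 to 614 ± 222 (1.86 ± 0.22, adjusted p = 3.76e-06). Hnf4a, a transcription factor of proximal tubule and liver, fell from 651 ± 60.8 to 396 ± 98.9 (-0.74 ± 0.13, adjusted p = 0.000558). Scd, the desaturase that makes monounsaturated fatty acids, had a signal of 828 ± 835 on the normal diet and 29.9 ± 8.85 on the high salt and fat diet (-3.93 ± 0.60, adjusted p = 0.000142). With the fat index as a covariate, a measure of fat tissue chosen after seeing the data, the Scd difference was -1.56 ± 0.39. Of 10208 probe sets tested, limma called 892 at an adjusted p under 0.05, of which 464 were higher and 428 lower. An unadjusted p under 0.05 was reached by 2328.

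The largest increase at 2 weeks was that of Psca, a membrane protein of urothelium and other epithelia, from 9.83 ± 8.32 to 153 ± 54.0 (3.24 ± 0.27, adjusted p = 9.93e-09). Aqp4, a basolateral water channel, followed at 1.97 ± 0.16, with 0.71 for its other probe set. Slco4a1, an organic anion transporter, rose by 1.49, with 0.95 for its other probe set, and Slc4a7, a sodium bicarbonate cotransporter, by 1.45. S100a6 and Tesc, which encode calcium-binding proteins, rose by 1.44 and 1.37, and Ppp1r1b by 1.32. Isyna1, the enzyme of inositol synthesis, rose by 1.21. Mrps6 had 1.20, a value of uncertain origin because the inositol transporter gene Slc5a3 lies within the span of Mrps6. After Scd, the largest decreases were those of Car3 (-3.44), Fabp4 (-2.58), Thrsp (-2.23), Cfd (-1.87), Alb (-1.66), Metrn (-1.59), Plin4 (-1.33), the mitochondrially encoded COX1 (-1.20) and Lpl (-1.17). All 6 high salt and fat arrays lay beyond the normal-diet median for each of these 20 genes, Akr1b1 included, because the rule that named them required it. Fabp4 was not called without any 1 of normal-diet arrays 2 and 3, or high salt and fat array 3 (-2.48 to -2.20), and Plin4 was not called without any 1 of normal-diet arrays 1, 2, 3 and 5, or high salt and fat arrays 1, 2, 3, 5 and 6 (-1.39 to -1.15).

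Collecting duct, osmolyte and thick ascending limb lists were higher at 2 weeks by camera. Of 12 collecting duct genes, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone. The collecting duct median was 0.31 (camera adjusted p = 3.43e-05, and adjusted p = 0.0689 with an estimated correlation). Aqp3, a further water channel, rose by 0.73 ± 0.08 and Fxyd4, a regulator of the sodium pump, by 1.02 ± 0.14, beside Aqp2 and Aqp4. Scnn1b, a subunit of the epithelial sodium channel, fell by 0.26 ± 0.08 (adjusted p = 0.0300), and was not called without any 1 of normal-diet arrays 1, 3 and 4, or high salt and fat array 5 (-0.26 to -0.21). Of 7 osmolyte and urea transport genes, 4 rose and 0 fell, or 4 and 1 adjusted over the list alone. The osmolyte and urea transport median was 0.47 (camera adjusted p = 0.0178, and adjusted p = 0.0689 with an estimated correlation). Besides Akr1b1 and Aqp2 these were the taurine transporter Slc6a6 (0.54 ± 0.12) and Nfat5, the transcription factor of the tonicity response (0.47 ± 0.11). The other probe sets of Slc6a6 and Nfat5 had adjusted p = 0.543 and 0.670. Of 8 thick ascending limb genes, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. The thick ascending limb median was 0.39 (camera adjusted p = 0.00321, and adjusted p = 0.172 with an estimated correlation). They included the sodium potassium chloride cotransporter Slc12a1 (0.54 ± 0.11) and the tight junction genes Cldn10 (0.41 ± 0.09) and Cldn19 (0.57 ± 0.13).

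The tubular injury list was higher at 2 weeks. Of 23 tubular injury genes, 7 rose and 0 fell, or 9 and 0 adjusted over the list alone. The tubular injury median was 0.23 (camera adjusted p = 0.000208, and adjusted p = 0.271 with an estimated correlation). Cd24 (0.79 ± 0.10), osteopontin Spp1 (0.93 ± 0.17) and Anxa2 (0.65 ± 0.14) rose beside S100a6. Havcr1, the gene of the injury marker KIM-1, and Lcn2, that of NGAL, were not called at 2 weeks (0.40 ± 0.33, adjusted p = 0.515 and 0.54 ± 0.22, adjusted p = 0.139). Fibronectin Fn1 was higher by 0.75 ± 0.13.

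Proximal tubule and fatty acid lists were lower at 2 weeks. Of 30 proximal tubule genes, 0 rose and 14 fell, or 1 and 18 adjusted over the list alone. The proximal tubule median was -0.24 (camera adjusted p = 9.61e-11, and adjusted p = 0.0689 with an estimated correlation). Besides Hnf4a, the argininosuccinate synthase gene Ass1 fell by 0.44 ± 0.08 and the gluconeogenic Fbp1 by 0.40 ± 0.08. Of 40 fatty acid oxidation and PPAR target genes, 3 rose and 12 fell, or 4 and 16 adjusted over the list alone. The fatty acid oxidation and PPAR target median was -0.15 (camera adjusted p = 3.95e-07, and adjusted p = 0.0689 with an estimated correlation). Pantetheinase Vnn1 (-0.75 ± 0.12), the peroxisomal Ehhadh (-0.67 ± 0.12) and the fatty acid hydroxylase Cyp4a1 (-0.53 ± 0.08) fell. Cpt1b, which carries long-chain fatty acids into mitochondria, rose by 0.78 ± 0.12, as did Bdh1 (0.88 ± 0.24), of ketone body metabolism, and the fatty acid binding protein Fabp3 (0.29 ± 0.09). Bdh1 was not called without high salt and fat array 2 (0.77), nor Fabp3 without any 1 of normal-diet arrays 1, 2, 3, 4 and 5, or high salt and fat arrays 1, 2, 4, 5 and 6 (0.20 to 0.29). Of 20 fatty acid synthesis genes, 0 rose and 4 fell, or 1 and 5 adjusted over the list alone. The fatty acid synthesis median was -0.12 (camera adjusted p = 0.000641, and adjusted p = 0.101 with an estimated correlation). With the fat index as a covariate the list was not called (adjusted p = 0.159). Acetyl-CoA carboxylase Acaca (-0.58 ± 0.13) fell with Scd and Thrsp.

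Drug metabolism and antioxidant lists were also lower at 2 weeks, with members that went both ways. Of 20 drug metabolism and organic ion transport genes, 1 rose and 5 fell, or 2 and 7 adjusted over the list alone. The drug metabolism and organic ion transport median was -0.03 (camera adjusted p = 0.0178, and adjusted p = 0.139 with an estimated correlation). Fmo1 fell by 0.34 ± 0.07 and Cyp2e1 by 0.52 ± 0.10, whereas the organic cation transporter Slc22a2 rose by 0.34 ± 0.10, a call absent without any 1 of normal-diet arrays 1 and 4, or high salt and fat arrays 2 and 3 (0.29 to 0.33). Of 28 NRF2 target and antioxidant genes, 2 rose and 3 fell, or 4 and 10 adjusted over the list alone. The NRF2 target and antioxidant median was -0.16 (camera adjusted p = 0.00957, and adjusted p = 0.111 with an estimated correlation). Glutathione peroxidase Gpx1 fell by 0.33 ± 0.07, whereas the glutathione transferases Gstp1 and Gsta3 rose by 0.42 ± 0.08 and 0.47 ± 0.12.

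Adipocyte and liver lists, markers of other tissues, were lower at 2 weeks. Of 6 adipocyte genes, 0 rose and 3 fell, or 0 and 5 adjusted over the list alone. The adipocyte median was -1.08 (camera adjusted p = 0.000208, and adjusted p = 0.137 with an estimated correlation). With the fat index as a covariate the direction turned for the adipocyte list, diet effect at 2 weeks (adjusted p = 0.877), as did those of Cfd (0.13) and Fabp4 (0.47), which are part of the index. Adrb3, the beta-3 adrenoceptor, had -0.87 ± 0.22, and the others were adipsin Cfd and the fatty acid binding protein Fabp4. Of 7 liver genes, 0 rose and 2 fell, or 0 and 2 adjusted over the list alone. The liver median was -0.35 (camera adjusted p = 0.00754, and adjusted p = 0.0689 with an estimated correlation). Alb, the gene of albumin, had signals of 76.4 ± 39.1 and 20.4 ± 16.6. Fabp4, Cfd and Car3 make the fat index. It was lower on the high salt and fat diet by a difference of -1.72 at 2 weeks (exact permutation p = 0.00866, adjusted p = 0.0173), below the normal-diet median in 6 of 6 arrays, and differed by 0.23 at 8 weeks (exact permutation p = 0.662). The index was chosen after seeing the data, from genes among the largest decreases at 2 weeks. Its difference at 2 weeks is thus no separate test of whether fat content differed. The Fabp4 call hung on single arrays, as given above.

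The ratio of 3' to 5' GAPDH signal, a measure of RNA integrity, was 1.22 ± 0.09 on the high salt and fat diet and 1.09 ± 0.07 on the normal diet at 2 weeks (exact permutation p = 0.0152, adjusted p = 0.0606 over 4 tests). The 18 probe sets of spiked bacterial and phage controls had a difference of -0.30 on the log2 scale at 2 weeks (exact permutation p = 0.00216, adjusted p = 0.00866 over 4 tests), lower in 6 of 6 arrays. With the fat index, the GAPDH ratio or the spike-in level as a covariate, each chosen after seeing the data, limma called 232, 328 and 482 probe sets in place of 892.

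**Figure D1:**
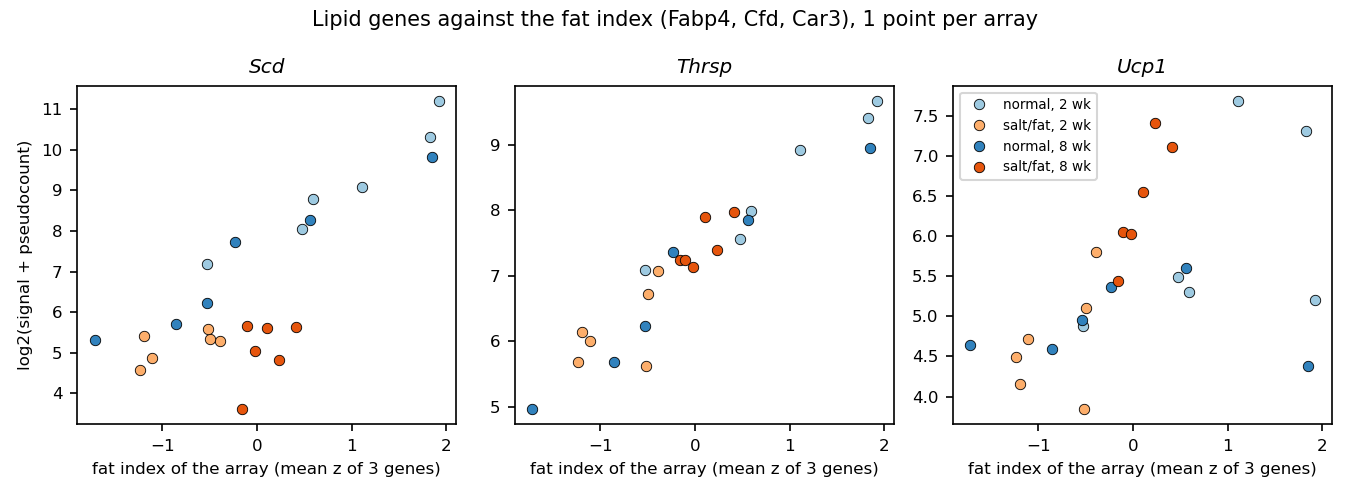
Log2 signals of Scd, Thrsp and Ucp1 on each of the 24 arrays against the fat index of the array, the mean standardised log2 signal of Fabp4, Cfd and Car3, with 1 point per animal coloured by group. The index differed by -1.72 between diets at 2 weeks and by 0.23 at 8 weeks, and Scd had a mean signal of 29.9 in the high salt and fat group at 2 weeks and 29.9 at 8 weeks.

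After 8 weeks the kidneys on the high salt and fat diet had higher transcripts of tubular injury, extracellular matrix, macrophages and antigen presentation. Transcripts of the proximal tubule, and of the list of the distal convoluted and connecting tubule, were lower. With an estimated correlation camera still called the first 4 of these lists, but not the proximal tubule list (adjusted p = 0.144) or the distal convoluted and connecting tubule list (adjusted p = 0.109). Havcr1 rose from a signal of 50.1 ± 13.4 to 466 ± 269 (2.88 ± 0.33, adjusted p = 2.2e-06), and Lcn2 from 42.4 ± 16.8 to 233 ± 87.1 (2.27 ± 0.22, adjusted p = 1.57e-07). Spp1 rose from 1142 ± 285 to 5334 ± 1663 (2.19 ± 0.17, adjusted p = 5.27e-09). Col1a1, a chain of fibrillar collagen, rose from 81.0 ± 19.8 to 311 ± 113 (1.80 ± 0.20, adjusted p = 1.11e-06), with 0.79 for its other probe set. Slc5a2, the glucose transporter SGLT2 of the early proximal tubule, fell from 732 ± 119.8 to 448 ± 86.2 (-0.71 ± 0.13, adjusted p = 0.000569). Limma called 933 probe sets, 575 higher and 358 lower, and 2416 had an unadjusted p under 0.05. Called changes of at least 2-fold were 58 upward and 2 downward, against 25 and 20 at 2 weeks.

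**Figure D2:**
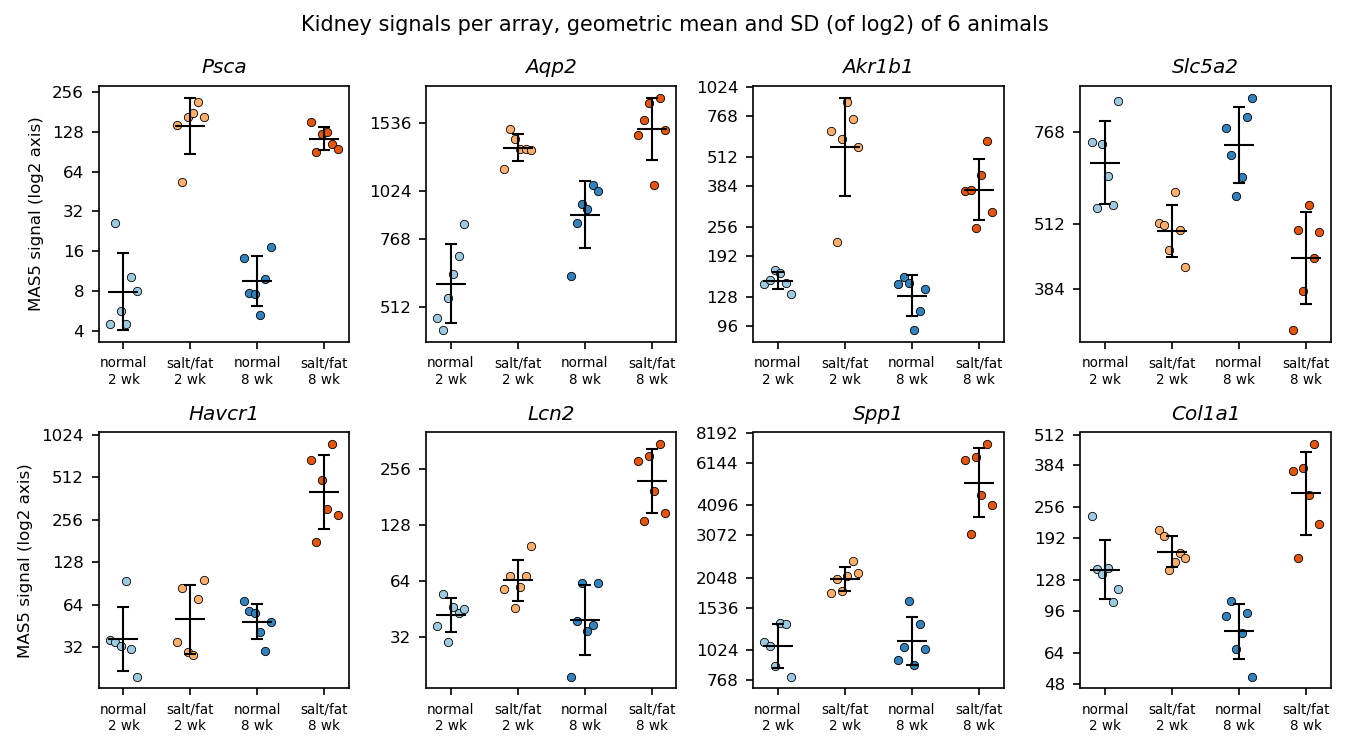
Signals of Psca, Aqp2, Akr1b1, Slc5a2, Havcr1, Lcn2, Spp1 and Col1a1 on each array, on log2 axes, by diet and weeks on the diet, where points are the 6 animals of a group and bars are the geometric mean with the SD of the log2 values. Havcr1 had a log2 fold change of 0.40 at 2 weeks and 2.88 at 8 weeks, whereas Psca had 3.24 and 2.82.

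Other large increases at 8 weeks were those of Psca (2.82), the calcium-binding S100a4 (2.17) and S100a6 (1.87), the tight junction gene Cldn3 (1.75), the elastic fibre gene Emilin1 (1.73) and Eml2 (1.72). The 10 largest decreases were Scd (-2.12 ± 0.60), the growth factor binding protein Igfbp3 (-1.01 ± 0.12), Gpr137 (-0.85), the acyl-CoA thioesterase Acot12 (-0.78), Slc5a2, Slc16a6 (-0.70), Ccdc126 (-0.66), proline dehydrogenase Prodh (-0.65), tissue factor F3 (-0.65) and Colq (-0.65). The other probe sets of Gpr137 and Slc16a6 had 0.20 and -0.35 and were not called. Scd was not called without any 1 of normal-diet arrays 1, 2 and 4, or high salt and fat arrays 1, 2 and 5 (-2.11 to -1.59). Eml2 was not called without any 1 of normal-diet arrays 1, 3 and 6, or high salt and fat arrays 1, 4 and 5 (1.47 to 1.74), and Prodh was not called without any 1 of normal-diet arrays 1 and 6, or high salt and fat arrays 1, 3 and 4 (-0.64 to -0.55). Clusterin Clu (1.11 ± 0.13) and heme oxygenase Hmox1 (1.26 ± 0.29) were higher at 8 weeks. Agt, Ace, the nephrin gene Nphs1, the uromodulin gene Umod, the thiazide-sensitive cotransporter Slc12a3, klotho Kl and Edn1 were called at neither time, with values from -0.41 for Kl at 2 weeks to 0.15 for Agt at 8 weeks. Umod had -0.02 at 2 weeks, and 0.21 after quantile normalization, where it was called.

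Injury, matrix and smooth muscle lists were higher at 8 weeks. Of 23 tubular injury genes, 17 rose and 0 fell, or 19 and 0 adjusted over the list alone. The tubular injury median was 0.90 (camera adjusted p = 2.21e-24, and adjusted p = 0.0108 with an estimated correlation). Cd24 had 1.15 ± 0.10, beside Havcr1, Lcn2, Spp1 and S100a6. Of 37 extracellular matrix and fibrosis genes, 15 rose and 1 fell, or 17 and 1 adjusted over the list alone. The extracellular matrix and fibrosis median was 0.28 (camera adjusted p = 1.15e-10, and adjusted p = 0.0485 with an estimated correlation). Fn1 (1.05 ± 0.13), Col3a1 (0.93 ± 0.14) and Col18a1 (0.61 ± 0.08) rose. The metalloproteinase inhibitor Timp3 fell by 0.34 ± 0.09, a call absent without high salt and fat array 5 (-0.27). Of 16 smooth muscle and pericyte genes, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone. The smooth muscle and pericyte median was 0.25 (camera adjusted p = 0.000472, and adjusted p = 0.0485 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, rose by 1.69 ± 0.21, and Tpm1 by 0.64 ± 0.09, with other probe sets at -0.03 and 0.77.

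Of the immune lists, 4 were higher at 8 weeks. Lymphocyte (4 genes measured, adjusted p = 0.0933) and chemokine and adhesion (adjusted p = 0.262) lists were not called. Of 19 macrophage and myeloid genes, 8 rose and 0 fell, or 11 and 0 adjusted over the list alone. The macrophage and myeloid median was 0.32 (camera adjusted p = 5.25e-09, and adjusted p = 0.0485 with an estimated correlation). Gpnmb (1.21 ± 0.17), the complement component C1qa (0.57 ± 0.09) and the lysosomal Cd68 (0.90 ± 0.14) rose. Of 22 antigen presentation genes, 10 rose and 0 fell, or 12 and 0 adjusted over the list alone. The antigen presentation median was 0.32 (camera adjusted p = 3.91e-09, and adjusted p = 0.0485 with an estimated correlation). The proteasome genes Psme1 (0.48 ± 0.06) and Psmb8 (0.83 ± 0.12) and the peptide transporter Tap2 (0.74 ± 0.14) rose. Of 15 interferon response genes, 6 rose and 0 fell, or 6 and 0 adjusted over the list alone. The interferon response median was 0.32 (camera adjusted p = 0.000136, and adjusted p = 0.199 with an estimated correlation). Ifitm1 (0.64 ± 0.08), Ifitm3 (0.49 ± 0.08) and Bst2 (0.74 ± 0.14) rose. Of 21 complement and coagulation genes, 6 rose and 1 fell, or 8 and 1 adjusted over the list alone. The complement and coagulation median was 0.20 (camera adjusted p = 0.00323, and adjusted p = 0.0855 with an estimated correlation). The fibrinogen chain Fga (1.58 ± 0.26), C1s (0.68 ± 0.12) and C3 (0.77 ± 0.15) rose and F3 fell.

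Stress, growth and adipocyte lists were also higher at 8 weeks. Of 13 heat shock genes, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone. The heat shock median was 0.25 (camera adjusted p = 0.000571, and adjusted p = 0.18 with an estimated correlation). Hspb1 (1.13 ± 0.13), Cryab (0.72 ± 0.12) and Hspa1a (1.24 ± 0.30) rose. Of 21 unfolded protein response genes, 4 rose and 0 fell, or 6 and 0 adjusted over the list alone. The unfolded protein response median was 0.26 (camera adjusted p = 0.00194, and adjusted p = 0.231 with an estimated correlation). The disulfide isomerase Pdia6 rose by 0.36 ± 0.08. Of 17 immediate early genes, 4 rose and 0 fell, or 4 and 0 adjusted over the list alone. The immediate early median was 0.26 (camera adjusted p = 0.0091, and adjusted p = 0.325 with an estimated correlation). The transcription factors Klf6 and Myc rose by 0.72 ± 0.16 and 0.96 ± 0.23. Of 16 proliferation genes, 2 rose and 0 fell, or 2 and 0 adjusted over the list alone. The proliferation median was 0.20 (camera adjusted p = 0.0067, and adjusted p = 0.118 with an estimated correlation). Of 6 adipocyte genes, 2 rose and 0 fell, or 2 and 0 adjusted over the list alone. The adipocyte median was 0.68 (camera adjusted p = 0.0113, and adjusted p = 0.268 with an estimated correlation). These were the brown fat genes Ucp1 (1.50 ± 0.42) and Cidea (1.28 ± 0.24). Ucp1 was not called without any 1 of normal-diet array 1, or high salt and fat arrays 1 and 4 (1.31 to 1.40), nor the adipocyte list without normal-diet array 6 (adjusted p 0.0518).

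Lists of the proximal and distal tubule and of their metabolism were lower at 8 weeks. Of 30 proximal tubule genes, 1 rose and 10 fell, or 1 and 14 adjusted over the list alone. The proximal tubule median was -0.18 (camera adjusted p = 6.35e-06, and adjusted p = 0.144 with an estimated correlation). The organic anion transporter Slc22a6 (-0.41 ± 0.08) and the fatty acid transporter Slc27a2 (-0.34 ± 0.07) fell, whereas guanine deaminase Gda rose by 0.70 ± 0.14, with adjusted p = 0.0683 for its other probe set. Of 6 distal convoluted and connecting tubule genes, 0 rose and 3 fell, or 0 and 3 adjusted over the list alone. The distal convoluted and connecting tubule median was -0.21 (camera adjusted p = 0.00997, and adjusted p = 0.109 with an estimated correlation). The calcium-binding Calb1 (-0.58 ± 0.10) and kallikrein Klk1 (-0.35 ± 0.09) fell. Of 16 vitamin D, calcium and phosphate genes, 1 rose and 4 fell, or 1 and 5 adjusted over the list alone. The vitamin D, calcium and phosphate median was -0.21 (camera adjusted p = 0.0166, and adjusted p = 0.0528 with an estimated correlation). Calb1 is a member of this list too, and the phosphate transporter Slc34a2 rose by 0.99 ± 0.16. Of 20 drug metabolism and organic ion transport genes, 0 rose and 6 fell, or 1 and 8 adjusted over the list alone. The drug metabolism and organic ion transport median was -0.23 (camera adjusted p = 0.000571, and adjusted p = 0.0485 with an estimated correlation). Fmo1 had -0.36 ± 0.07. Of 40 fatty acid oxidation and PPAR target genes, 4 rose and 4 fell, or 4 and 9 adjusted over the list alone. The fatty acid oxidation and PPAR target median was -0.08 (camera adjusted p = 0.0236, and adjusted p = 0.325 with an estimated correlation). Acot12 and Cyp4a1 (-0.36 ± 0.08) were among those that fell. Angptl4, an inhibitor of lipoprotein lipase, rose by 0.84 ± 0.23, a call absent without any 1 of normal-diet array 6, or high salt and fat arrays 1 and 5 (0.71 to 0.73). The fatty acid oxidation list was not called without any 1 of normal-diet arrays 1, 4 and 5, or high salt and fat array 5 (adjusted p 0.0509 to 0.0789).

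Collecting duct and thick ascending limb lists were higher at 8 weeks. Of 12 collecting duct genes, 4 rose and 0 fell, or 6 and 2 adjusted over the list alone. The collecting duct median was 0.24 (camera adjusted p = 0.0091, and adjusted p = 0.144 with an estimated correlation). Aqp4 (1.15 ± 0.16, with an uncalled 0.55 for its other probe set), Aqp2 (0.73 ± 0.14) and Fxyd4 (0.67 ± 0.14) rose. Of 8 thick ascending limb genes, 2 rose and 0 fell, or 3 and 0 adjusted over the list alone. The thick ascending limb median was 0.37 (camera adjusted p = 0.00376, and adjusted p = 0.18 with an estimated correlation). Cldn19 rose by 0.61 ± 0.13. Akr1b1 rose by 1.46 ± 0.22, while the osmolyte and urea transport list was not called (adjusted p = 0.172, with a median of -0.04 and a mean of 0.27). Across both times, 170 probe sets were higher at 2 and at 8 weeks where independent calls would share 26.1, and 107 were lower where 15.0 would be shared. Opposite directions were found for 5, where independent calls would give 40.4. Changes at both times had a Pearson correlation of 0.437 across the 10208 probe sets, which are not independent replicates.

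The spike-in controls were higher by 0.23 on the high salt and fat diet at 8 weeks (exact permutation p = 0.0476, adjusted p = 0.0476). The 933 calls at 8 weeks became 543 without high salt and fat array 1 and 579 without array 5. They became 541 without normal-diet arrays 1 and 2, whose low signals were raised, and 497 with the spike-in level as a covariate, both chosen after seeing the data.

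**Figure D3:**
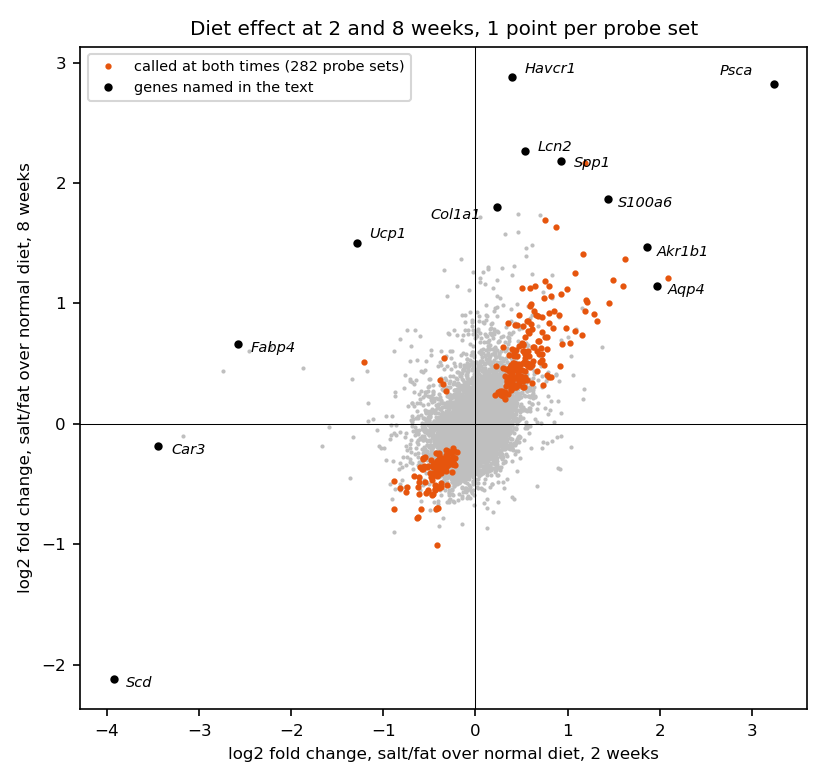
Log2 fold change of the high salt and fat diet against the normal diet at 2 weeks (horizontal axis) and at 8 weeks (vertical axis), 1 point per probe set, with probe sets called at both times in colour and labelled examples of the genes named in the text in black. Most probe sets called at both times lie in the quadrants of equal direction, with 170 higher, 107 lower and 5 opposite.

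The interaction of diet and time, the test of whether the diet effect differed between 2 and 8 weeks, showed a larger effect at 8 weeks for injury and macrophage genes. Havcr1 had a difference of 2.48 ± 0.47, adjusted p = 0.0155, and Lcn2 had 1.73 ± 0.32, adjusted p = 0.0113. Spp1 differed by 1.25 ± 0.24, Clu by 1.19 ± 0.19, and Col1a1 by 1.57 ± 0.28, with an uncalled 0.62 for its other probe set. COX1 had signals of 5220.4 ± 684 on the normal diet and 2279.8 ± 448 on the high salt and fat diet at 2 weeks, and 4581 ± 1936 and 6226 ± 779 at 8 weeks (1.72 ± 0.23, adjusted p = 0.000306). Limma called 39 probe sets, 35 with a more positive and 4 with a more negative effect at 8 weeks, and 1189 had an unadjusted p under 0.05.

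The largest positive differences were those of Ucp1 (2.79 ± 0.59), Havcr1, Lcn2, COX1 and Cidea (1.62 ± 0.33). Negative were Nae1 (-0.80 ± 0.16), the proximal sodium proton exchanger Slc9a3 (-0.68 ± 0.12), Tmtc1 (-0.59 ± 0.12) and Gcnt2 (-0.59 ± 0.12). Ucp1 was not called without any 1 of 2-week normal-diet array 2, or 2-week high salt and fat array 3, or 8-week high salt and fat array 1 (2.52 to 2.75), nor Tmtc1 without 8-week high salt and fat array 3 (-0.55). Of 19 macrophage and myeloid genes, 4 were called upward and 0 downward, or 10 and 0 adjusted over the list alone. The macrophage and myeloid median was 0.52 (camera adjusted p = 7.75e-15, and adjusted p = 0.0139 with an estimated correlation). They included Cd68 (1.05 ± 0.20) and C1qa (0.62 ± 0.12). Of 23 tubular injury genes, 6 were called upward and 0 downward, or 12 and 0 adjusted over the list alone. The tubular injury median was 0.50 (camera adjusted p = 7.75e-15, and adjusted p = 0.0277 with an estimated correlation). Of 22 antigen presentation genes, 3 were called upward and 0 downward, or 13 and 1 adjusted over the list alone. The antigen presentation median was 0.33 (camera adjusted p = 2.07e-11, and adjusted p = 0.0269 with an estimated correlation). The class II gene RT1-Da had 0.89 ± 0.16. Of 37 extracellular matrix and fibrosis genes, 2 were called upward and 0 downward, or 6 and 0 adjusted over the list alone. The extracellular matrix and fibrosis median was 0.25 (camera adjusted p = 1.35e-08, and adjusted p = 0.0621 with an estimated correlation). Of 6 adipocyte genes, 2 were called upward and 0 downward, or 6 and 0 adjusted over the list alone. The adipocyte median was 1.98 (camera adjusted p = 6.26e-10, and adjusted p = 0.0269 with an estimated correlation).

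Other lists shifted in the interaction with fewer called genes. Of 15 interferon response genes, 1 was called upward and 0 downward, or 3 and 0 adjusted over the list alone. The interferon response median was 0.26 (camera adjusted p = 5.21e-06, and adjusted p = 0.183 with an estimated correlation). Bst2 was that gene (1.03 ± 0.20). Of 16 smooth muscle and pericyte genes, 1 was called upward and 0 downward, or 2 and 1 adjusted over the list alone. The smooth muscle and pericyte median was 0.23 (camera adjusted p = 0.00155, and adjusted p = 0.0621 with an estimated correlation). Rgs5, a pericyte gene, had 1.09 ± 0.23 and was not called without any 1 of 2-week normal-diet array 1, or 8-week normal-diet array 4, or 8-week high salt and fat arrays 3 and 5 (1.00 to 1.06). The NRF2 target and antioxidant list (median 0.12, adjusted p = 0.000744, and adjusted p = 0.039 with an estimated correlation) and the lymphocyte list (median 0.42, adjusted p = 0.00248, and adjusted p = 0.0599 with an estimated correlation) shifted upward with 0 called genes each, or 0 and 2 upward adjusted over the list alone. Only 4 of the 35 lymphocyte genes were measured. Upward shifts were also called for complement and coagulation (median 0.11, adjusted p = 0.00248, and adjusted p = 0.0621 with an estimated correlation), fatty acid oxidation (median 0.08, adjusted p = 0.00735, and adjusted p = 0.286 with an estimated correlation) and the unfolded protein response (median 0.13, adjusted p = 0.00735, and adjusted p = 0.308 with an estimated correlation). Heat shock (median 0.20, adjusted p = 0.0104, and adjusted p = 0.308 with an estimated correlation), immediate early genes (median 0.10, adjusted p = 0.0306, and adjusted p = 0.401 with an estimated correlation) and fatty acid synthesis (median 0.07, adjusted p = 0.0411, and adjusted p = 0.286 with an estimated correlation) were called upward too. With the fat index as a covariate the direction turned for fatty acid oxidation (adjusted p = 0.670), immediate early genes (adjusted p = 0.949) and fatty acid synthesis (adjusted p = 0.949). The collecting duct list shifted downward (median -0.18, adjusted p = 0.014, and adjusted p = 0.185 with an estimated correlation), with Aqp4 at -0.82 ± 0.23, adjusted p = 0.145.

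The 39 calls became 22 without high salt and fat array 3 of 8 weeks, 80 with array weights, and 13, 4 and 0 in limma with the fat index, the GAPDH ratio and the spike-in level as a covariate, where 1189 probe sets had an unadjusted p under 0.05 without a covariate. The 39 kept a median of 96.6, 90.9 and 99.8% of their effect with these covariates, all in the same direction, while the SE grew 1.20, 1.08 and 1.36 times. Fatty acid synthesis was not called without any 1 of 2-week normal-diet arrays 1, 2 and 3, or 2-week high salt and fat arrays 2, 3, 4 and 6, or 8-week normal-diet arrays 2 and 3, or 8-week high salt and fat arrays 4 and 6 (adjusted p 0.0515 to 0.126). Immediate early genes were not called without any 1 of 2-week normal-diet array 2, or 2-week high salt and fat arrays 2, 3 and 6, or 8-week normal-diet arrays 2 and 5, or 8-week high salt and fat array 1 (adjusted p 0.0638 to 0.196). Heat shock was not called without any 1 of 8-week high salt and fat arrays 1 and 2 (adjusted p 0.0528 to 0.0543), fatty acid oxidation without 2-week normal-diet array 1 (adjusted p 0.0509), and collecting duct without 2-week normal-diet array 1 (adjusted p 0.0518).

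**Figure D4:**
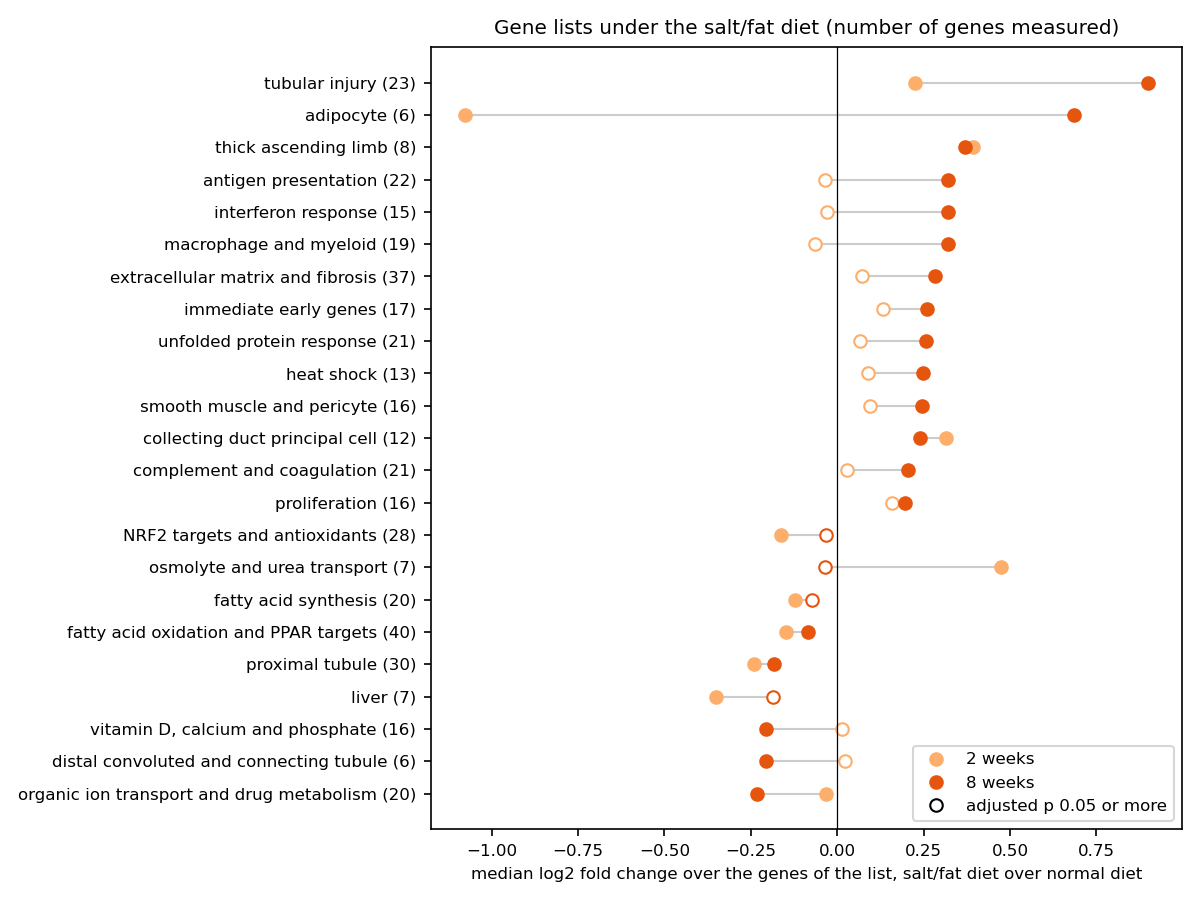
Median log2 fold change of the measured genes of each list called in either diet comparison, at 2 weeks and at 8 weeks, with filled points for a camera adjusted p under 0.05 and open points otherwise. The tubular injury median was 0.23 at 2 weeks and 0.90 at 8 weeks, and the proximal tubule median was -0.24 and -0.18.

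On the normal diet few transcripts differed between 2 and 8 weeks, a comparison of animals that also differ in age. Grem1, a secreted BMP antagonist, rose from 100.4 ± 52.2 to 229 ± 49.0 (1.26 ± 0.22, adjusted p = 0.0262). Csrp1 rose by 0.44 ± 0.08 (adjusted p = 0.0276) and Aqp3 by 0.43 ± 0.08 (adjusted p = 0.0488). Ccm2 fell from 111 ± 25.4 to 39.3 ± 30.2 (-1.53 ± 0.27, adjusted p = 0.0262). Limma called these 4 probe sets and no others, and 869 had an unadjusted p under 0.05. Grem1 was not called without any 1 of 2-week normal-diet arrays 1, 2 and 4, or 8-week normal-diet arrays 2, 3, 4, 5 and 6 (1.07 to 1.28), Csrp1 without any 1 of 2-week normal-diet arrays 1, 3, 4 and 5, or 8-week normal-diet arrays 2, 3, 4, 5 and 6 (0.40 to 0.46), Aqp3 without any 1 of 2-week normal-diet arrays 1, 2, 4 and 5, or 8-week normal-diet arrays 2, 3, 4, 5 and 6 (0.39 to 0.43), and Ccm2 without any 1 of 2-week normal-diet arrays 1, 4 and 5, or 8-week normal-diet arrays 2, 3, 4 and 6 (-1.54 to -1.35). Leaving out 1 array gave from 0 to 10 calls, and limma made 0 calls without the intensity trend, with those groups alone, or with the fat index, GAPDH ratio or spike-in level as a covariate. With these covariates the 4 probe sets kept a median of 83.6, 95.2 and 97.6% of their effect, all in the same direction, while the SE grew 1.07, 1.05 and 1.22 times.

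Lists of fatty acid oxidation (median -0.12, adjusted p = 4.73e-09, and adjusted p = 0.0508 with an estimated correlation), adipocytes (median -1.10, adjusted p = 2.39e-07, and adjusted p = 0.0755 with an estimated correlation) and NRF2 targets (median -0.12, adjusted p = 0.000175, and adjusted p = 0.0508 with an estimated correlation) shifted downward with time on the normal diet. The proximal tubule list (median -0.09, adjusted p = 0.000588, and adjusted p = 0.378 with an estimated correlation) and the extracellular matrix list (median -0.08, adjusted p = 0.000588, and adjusted p = 0.376 with an estimated correlation) did as well. None of their genes was called over all probe sets. Adjusted over the list alone, 4 fatty acid oxidation, 6 of 6 adipocyte and 3 extracellular matrix genes were lower. The mean fat index fell too, from 0.90 to -0.15, so carried fat stays open. Eci2 had -0.24 ± 0.06, Cpt2 -0.35 ± 0.09, Lipe -1.45 ± 0.33, Gclm -0.26 ± 0.08, Col1a1 -0.79 ± 0.20 and Col3a1 -0.56 ± 0.14. Fatty acid synthesis (median -0.08, adjusted p = 0.0156, and adjusted p = 0.348 with an estimated correlation), drug metabolism (median -0.06, adjusted p = 0.0156, and adjusted p = 0.235 with an estimated correlation), interferon response (median -0.15, adjusted p = 0.0451, and adjusted p = 0.705 with an estimated correlation) and oxidative phosphorylation (median -0.04, adjusted p = 0.0451, and adjusted p = 0.705 with an estimated correlation) were called downward with larger p values. The direction of oxidative phosphorylation turned with quantile normalization (adjusted p = 0.334) and with the spike-in level as a covariate (adjusted p = 0.769). Fatty acid synthesis was not called without any 1 of 2-week normal-diet arrays 1, 2 and 3, or 8-week normal-diet array 2 (adjusted p 0.0588 to 0.0843). Interferon response was not called without any 1 of 2-week normal-diet arrays 3 and 4, or 8-week normal-diet arrays 4, 5 and 6 (adjusted p 0.0697 to 0.783), nor oxidative phosphorylation without any 1 of 2-week normal-diet arrays 1 and 6, or 8-week normal-diet arrays 1, 2 and 3 (adjusted p 0.0867 to 0.376). The spike-in controls had a difference of -0.30 between 8 and 2 weeks on the normal diet (exact permutation p = 0.0152, adjusted p = 0.0202).

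On the high salt and fat diet, injury, macrophage, antigen presentation and smooth muscle genes were higher at 8 than at 2 weeks. Havcr1 rose by 2.82 ± 0.33, adjusted p = 1.11e-05, and Lcn2 rose by 1.66 ± 0.22, adjusted p = 5.32e-05. Clu rose by 1.34 ± 0.13, Spp1 by 1.33 ± 0.17, the metalloproteinase inhibitor Timp1 by 1.36 ± 0.20, and the galectin gene Lgals3 by 1.11 ± 0.19. Calb1 fell from 1447 ± 107 to 831 ± 184 (-0.82 ± 0.10, adjusted p = 1.76e-05). Limma called 360 probe sets, 227 higher and 133 lower, and 1731 had an unadjusted p under 0.05. The higher share of calls was 63.1%, and it was 46.6% when each array was centred on its median.

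The 5 largest increases over time on the high salt and fat diet were Havcr1, Metrn (1.88 ± 0.30), Ucp1 (1.74 ± 0.42), Lcn2 and Hmox1 (1.47 ± 0.29). The 5 largest decreases were Lrch4 (-0.93 ± 0.22), Dusp23 (-0.87 ± 0.22), Calb1, the Notch ligand Jag1 (-0.80 ± 0.22) and Anp32a (-0.80 ± 0.18). Jag1 was not called without any 1 of 2-week high salt and fat arrays 1, 2, 3, 4 and 5, or 8-week high salt and fat arrays 1, 3, 4, 5 and 6 (-0.83 to -0.66). Of 23 tubular injury genes, 16 rose and 0 fell, or 17 and 1 adjusted over the list alone. The tubular injury median was 0.71 (camera adjusted p = 2.23e-21, and adjusted p = 0.0104 with an estimated correlation). Of 19 macrophage and myeloid genes, 12 rose and 0 fell, or 15 and 0 adjusted over the list alone. The macrophage and myeloid median was 0.49 (camera adjusted p = 2.97e-18, and adjusted p = 0.00473 with an estimated correlation). Gpnmb (1.19 ± 0.17) and C1qa (0.52 ± 0.09) rose. Of 22 antigen presentation genes, 10 rose and 1 fell, or 17 and 1 adjusted over the list alone. The antigen presentation median was 0.29 (camera adjusted p = 3.76e-11, and adjusted p = 0.0215 with an estimated correlation). RT1-Da rose by 0.69 ± 0.11 and B2m by 0.34 ± 0.07, whereas the class I gene RT1-CE16 fell by 0.44 ± 0.09. Of 16 smooth muscle and pericyte genes, 4 rose and 0 fell, or 7 and 0 adjusted over the list alone. The smooth muscle and pericyte median was 0.28 (camera adjusted p = 1.97e-06, and adjusted p = 0.0108 with an estimated correlation). Tagln rose by 1.23 ± 0.21 and Acta2, the gene of smooth muscle actin, by 0.63 ± 0.12. Of 21 complement and coagulation genes, 3 rose and 0 fell, or 4 and 0 adjusted over the list alone. The complement and coagulation median was 0.20 (camera adjusted p = 0.000445, and adjusted p = 0.0363 with an estimated correlation). Complement factor I, Cfi, rose by 0.96 ± 0.19. Of 37 extracellular matrix and fibrosis genes, 3 rose and 1 fell, or 5 and 1 adjusted over the list alone. The extracellular matrix and fibrosis median was 0.16 (camera adjusted p = 0.000262, and adjusted p = 0.241 with an estimated correlation). Fbln5, of elastic fibres, fell by 0.40 ± 0.09.

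Chemokines and adhesion (median 0.21, adjusted p = 0.00404, and adjusted p = 0.0442 with an estimated correlation), lymphocytes (median 0.42, adjusted p = 0.00084, and adjusted p = 0.0363 with an estimated correlation), interferon response (median 0.22, adjusted p = 0.00072, and adjusted p = 0.304 with an estimated correlation) and adipocytes (median 0.95, adjusted p = 0.000953, and adjusted p = 0.214 with an estimated correlation) were called upward between 2 and 8 weeks on the high salt and fat diet. Cxcl16 rose by 0.37 ± 0.09 and Bst2 by 1.08 ± 0.14. The mean fat index rose too, from -0.82 to 0.08, so carried fat stays open. Heat shock (median 0.17, adjusted p = 0.00367, and adjusted p = 0.304 with an estimated correlation), the unfolded protein response (median 0.12, adjusted p = 0.0156, and adjusted p = 0.453 with an estimated correlation), immediate early genes (median 0.16, adjusted p = 0.0206, and adjusted p = 0.457 with an estimated correlation) and liver (median 0.18, adjusted p = 0.0472, and adjusted p = 0.175 with an estimated correlation) were also called upward. Hspb1 rose by 0.67 ± 0.13. Drug metabolism (median -0.17, adjusted p = 0.00084, and adjusted p = 0.0442 with an estimated correlation), oxidative phosphorylation (median -0.08, adjusted p = 0.00072, and adjusted p = 0.304 with an estimated correlation) and distal convoluted and connecting tubule (median -0.10, adjusted p = 0.0244, and adjusted p = 0.175 with an estimated correlation) were called downward. Slco1a6 fell by 0.50 ± 0.12. Liver was not called without any 1 of 2-week high salt and fat arrays 2, 3, 4 and 6, or 8-week high salt and fat arrays 1, 2 and 6 (adjusted p 0.054 to 0.225). The unfolded protein response was not called without any 1 of 2-week high salt and fat arrays 2 and 4, or 8-week high salt and fat arrays 1 and 4 (adjusted p 0.0525 to 0.111), immediate early genes without any 1 of 2-week high salt and fat arrays 2 and 6, or 8-week high salt and fat array 1 (adjusted p 0.0647 to 0.109), and distal convoluted and connecting tubule without any 1 of 2-week high salt and fat array 2, or 8-week high salt and fat array 5 (adjusted p 0.0788 to 0.0993).

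The 360 calls became 233 without high salt and fat array 3 of 2 weeks, 220 without array 5 of 8 weeks, 223 with those groups alone and 632 with array weights. The spike-in controls had a difference of 0.23 between 8 and 2 weeks on this diet (exact permutation p = 0.00866, adjusted p = 0.0173).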

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

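The splits and the tests of medulla, fat, RNA quality and hybridization were chosen only after the results were seen, as were the covariates and the omission of normal-diet arrays 1 and 2, an omission whose expected outcome was set before its own result was seen. In 100 splits of the same arrays into groups of equal size, the real split included, the 892 calls for diet at 2 weeks were reached by 1 split (highest other 72). The 933 at 8 weeks were reached by 1 (highest other 267), and the 360 for time on the high salt and fat diet by 1 (highest other 197), so chance can be excluded for these. The 39 of the interaction were reached by 1 (highest other 5). Splits for the interaction shuffled the diets within each time, which also removes the diet effect common to both times and moves it into the spread. They therefore cannot decide whether chance gave a difference between the diet effects. For the 4 calls over time on the normal diet 2 splits, the real one included, gave as many (highest other 19), under a bound of 5 in 100. Chance cannot be excluded for them, since another split gave several times the real count and leaving out single arrays gave 0 to 10 calls. Limma also made 0 calls without the intensity trend or with any of the covariates. The 16 lists of the interaction were reached by 3 splits (highest other 17), with the same limit of the shuffling. For lists, chance can be excluded at 8 weeks (19 lists, reached by 1 split, highest other 16). The 17 lists over time on the high salt and fat diet were reached by 4 splits, the real one included (highest other 17), under the bound of 5 in 100. Chance cannot be excluded for them, since other splits gave as many. Nor can it be excluded for the 11 lists at 2 weeks (reached by 10, highest other 13) or the 9 lists over time on the normal diet (reached by 5, highest other 10).

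At 2 weeks on the high salt and fat diet, collecting duct and osmolyte genes were higher and proximal tubule genes lower, with a score of the former minus the latter that differed by 0.679 ± 0.070. Uneven amounts of medulla among the whole-kidney samples would make medulla markers deviate together within groups. The mean residual correlation of 10 markers was 0.0210, below the 0.0588 reached by 5% of permutations. The score difference was 0.689 ± 0.084 with the GAPDH ratio and 0.606 ± 0.083 with the spike-in level as a covariate. What these track within groups is not the whole cause, but RNA or hybridization effects aligned with diet stay open. The markers did not move alike, since Aqp4 had 1.97 ± 0.16 and Scnn1b -0.26 ± 0.08. Markers need not be equally confined to the medulla, so neither this nor the correlation decides. Uneven amounts or a larger share in all 6 kidneys stay open. A candidate explanation from the design is a response of the collecting duct to the salt load, which was not tested apart from fat, and the score differed by 0.411 at 8 weeks.

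Fat-related transcripts moved in 3 ways. The 6 fat markers Fabp4, Cfd, Car3, Lipe, Plin4 and Thrsp deviated together within groups, with a mean residual correlation of 0.781 against 0.136 in permutations, as uneven amounts of fat tissue carried with the kidney would give; Car3 had 1105 ± 865 on the normal diet and 74.5 ± 37.4 on the high salt and fat diet at 2 weeks, Cfd and Thrsp are also in the complement and fatty acid synthesis lists, how many of the 6 the kidney itself expresses is not known here, and a diet effect on fat in or around the kidney stays open and untested. For Scd the difference at 8 weeks was -2.44 ± 0.30 with the fat index and -2.12 ± 0.70 without it (ordinary SE, 0.60 in limma). Under a common slope uneven fat alone does not give this. At 2 weeks much went with the index, from -3.93 to -1.56 ± 0.39. Lower Scd within the carried fat stays open. For Ucp1 and Cidea at 8 weeks, fat tissue and a change in the kidney cannot be told apart, since their diet difference minus that of Fabp4, Cfd and Car3 was 1.08 (exact permutation p = 0.158) with an SD of 1.74 on the normal diet. Salt and fat were given together, so dietary fat as a suppressor of lipid synthesis is a candidate explanation for Scd that was not tested apart from salt.

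Normal-diet arrays 1 and 2 at 8 weeks had raised low signals, and leaving out both gave 541 calls for diet at 8 weeks in place of 933, of which 479 were shared. Leaving out any of the other 14 pairs of 8-week normal-diet arrays gave 462 to 926 calls, with 440 to 733 shared, and 4 of those pairs gave as few calls. The outcome set for the raised low signals, fewer calls than without any other pair and most calls lost, was thus not met. Those 4 pairs all held array 1 or 2, while the pairs with neither gave 666 to 926 calls, so that a part of these 2 arrays in the calls cannot be excluded, and a diet effect stays open for the 479 shared calls as a hypothesis.

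Single arrays stood apart from the other 5 of their group, by a gap above the critical value of Dixon's test, in 33 of 736 groups of values, where chance gives about 1 in 20. Among high salt and fat arrays of 2 weeks, array 2 was lowest for Akr1b1 (signal 221), Kl (31.3) and Psca (53.2) and highest for the ratio of 3' to 5' actin (2.27). Array 4 was lowest for Aqp3 (459.3), array 5 highest for Cpt1b (269.9), and array 6 highest for the proliferation score (0.863). Among normal-diet arrays of 2 weeks, array 1 was highest for Slc34a1 (6017.6) and lowest for Umod (5168) and the collecting duct score (-1.16). Array 4 of this group was highest for Fga (62.2), Havcr1 (94.7) and Psme1 (825.5), and array 6 was highest for Fabp3 (952.4) and lowest for the extracellular matrix score (-0.594). On the normal diet at 8 weeks, array 1 was lowest for Aqp3 (344.2) and the collecting duct score (-0.753) and highest for Lpl (586.3), and array 2 was lowest for Fabp3 (691.2). Array 3 there was lowest for Metrn (37.3) and Slc12a3 (463.2) and highest for Ppp1r1b (130.0). Array 4 was highest for Coro1a (69.9), array 5 highest for COX1 (8425.2) and lowest for Fdps (317), and array 6 lowest for Gstp1 (720.5). On the high salt and fat diet at 8 weeks, array 1 was lowest for Add3 (595.6), array 2 highest for Alb (162.3) and lowest for Psmb8 (127.8) and the antigen presentation score (-0.164), and array 3 lowest for Insig1 (169.8). Array 5 was lowest for Dusp23 (15.6), and array 6 highest for RT1-CE16 (280.8).

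The diet effect differed between 8 and 2 weeks by the interaction test for named genes. In tubular injury these were Havcr1 (2.48), Lcn2 (1.73), Clu (1.19), Spp1 (1.25) and Gpnmb (1.15). In the myeloid, antigen presentation and interferon lists they were Cd68 (1.05), C1qa (0.62), Lyz2 (0.52), RT1-Da (0.89), Tap2 (0.87), B2m (0.42, with an uncalled 0.19 for its other probe set) and Bst2 (1.03). Among the others Col1a1 had 1.57, Col3a1 0.91, Rgs5 1.09, COX1 1.72, Ucp1 2.79, Cidea 1.62, Nae1 -0.80, Slc9a3 -0.68, Tmtc1 -0.59 and Gcnt2 -0.59. B2m was not called without any 1 of 2-week normal-diet arrays 1, 2, 3 and 4, or 2-week high salt and fat arrays 1, 2, 3 and 5, or 8-week normal-diet arrays 2, 3, 5 and 6, or 8-week high salt and fat arrays 1, 3, 5 and 6 (0.39 to 0.43). Tap2 was not called without any 1 of 2-week normal-diet arrays 1, 2, 4 and 5, or 2-week high salt and fat arrays 1 and 3, or 8-week normal-diet arrays 2, 4 and 6, or 8-week high salt and fat arrays 3, 4, 5 and 6 (0.79 to 0.89). Col3a1 (0.86 to 0.88) was uncalled without 2-week array 3 of either diet, or 8-week normal-diet array 6 or high salt and fat array 3. Rgs5 (1.00 to 1.06) and Ucp1 (2.52 to 2.75) were not called without any 1 of their arrays given above. Lyz2 was not called without any 1 of 8-week normal-diet array 2, or 8-week high salt and fat array 3 (0.50 to 0.51). Without 8-week high salt and fat array 3, Gpnmb had 1.06 and Tmtc1 -0.55 and neither was called.

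For the same difference camera called 16 lists, and 5 with an estimated correlation (tubular injury, macrophage and myeloid, antigen presentation, NRF2 targets and adipocyte). Medians of the 16 were 1.98 for adipocyte, 0.52 for macrophage and myeloid, 0.50 for tubular injury, 0.42 for lymphocyte, 0.33 for antigen presentation and 0.26 for interferon response. Medians were 0.25 for extracellular matrix, 0.23 for smooth muscle and pericyte, 0.20 for heat shock, 0.13 for the unfolded protein response, 0.12 for NRF2 targets and 0.11 for complement and coagulation. For immediate early genes the median was 0.10, for fatty acid oxidation 0.085, for fatty acid synthesis 0.067 and for collecting duct -0.18. Fatty acid synthesis was not called without any 1 of 2-week normal-diet arrays 1, 2 and 3, or 2-week high salt and fat arrays 2, 3, 4 and 6, or 8-week normal-diet arrays 2 and 3, or 8-week high salt and fat arrays 4 and 6 (adjusted p 0.0515 to 0.126). Immediate early genes were not called without any 1 of 2-week normal-diet array 2, or 2-week high salt and fat arrays 2, 3 and 6, or 8-week normal-diet arrays 2 and 5, or 8-week high salt and fat array 1 (adjusted p 0.0638 to 0.196). Heat shock was not called without any 1 of 8-week high salt and fat arrays 1 and 2 (adjusted p 0.0528 to 0.0543), fatty acid oxidation without 2-week normal-diet array 1 (adjusted p 0.0509), nor collecting duct without 2-week normal-diet array 1 (adjusted p 0.0518). The spike-in controls, outside the genes compared, had a diet difference of -0.30 at 2 weeks and 0.23 at 8 weeks. The labels give no hybridization dates, and a hybridization batch aligned with the groups cannot be excluded for the interaction, whose 39 calls became 0 with the spike-in level as a covariate while 99.8% of the effect was kept and the SE grew 1.36 times.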

How the results depend on the processing

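The covariates and the omission of both normal-diet arrays with raised low signals were chosen after seeing the data. For diet at 2 weeks the 892 calls became 232 with the fat index, 328 with the GAPDH ratio and 482 with the spike-in level as a covariate, and were 598 to 986 without single arrays. The called probe sets kept a median of 94.6, 91.4 and 101% of their effect with these covariates while the SE grew 1.31, 1.17 and 1.24 times, in keeping with a loss of calls through wider errors. For diet at 8 weeks the 933 calls became 541 without both arrays and 497 with the spike-in level (97.3% of the effect kept, SE 1.15 times), and 543 (without high salt and fat array 1) to 1120 without single arrays. The 39 interaction calls became 80 with array weights, 13 with the fat index, 4 with the GAPDH ratio and 0 with the spike-in level in limma, where 1189 had an unadjusted p under 0.05 without it (96.6, 90.9 and 99.8% of the effect kept, SE 1.20, 1.08 and 1.36 times), and 22 (without 8-week high salt and fat array 3) to 50 without single arrays. The 4 calls over time on the normal diet became 9 without both arrays, 2 with centring, and 0 without the trend, with any of the covariates or with those groups alone in limma, and 0 to 10 without single arrays (83.6, 95.2 and 97.6% of the effect kept with the fat index, GAPDH ratio and spike-in level, SE 1.07, 1.05 and 1.22 times); 869 had an unadjusted p under 0.05. The 360 over time on the high salt and fat diet became 632 with array weights and 223 with those groups alone, and 220 (without 8-week array 5) to 507 without single arrays. Where no value above shows it, the cause was not tested.

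Lists called with an estimated correlation were 0 of 11 for diet at 2 weeks, 6 of 19 at 8 weeks, 5 of 16 in the interaction, 0 of 9 over time on the normal diet and 8 of 17 over time on the high salt and fat diet. Single arrays left out gave 11 to 12, 18 to 21, 13 to 18, 7 to 10 and 13 to 17 lists. The mixed test of fry, which asks for change in either direction, called 22 lists at 2 weeks, 10 in the interaction and 4 over time on the normal diet. For the last, directional fry called 3, the fat index left 4 and quantile normalization 5.

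Directions reversed at 2 weeks with the fat index for Cfd (0.13) and Fabp4 (0.47), which are part of the index, and for the adipocyte list, diet effect at 2 weeks (adjusted p = 0.877). Umod at 2 weeks had 0.21 with quantile normalization. In the interaction fatty acid oxidation (adjusted p = 0.670), fatty acid synthesis (0.949) and immediate early genes (0.949) reversed with the fat index. Oxidative phosphorylation over time on the normal diet reversed with quantile normalization (adjusted p = 0.334) and with the spike-in level (0.769). The cause was not tested. Over all 6223 comparisons of 223 gene results with an alternative, 5789 kept direction and side of the threshold, 420 lost the call, 11 gained it and 3 reversed. Over 1848 comparisons of 72 list results, 1643 kept both, 199 lost the call, 0 gained it and 6 reversed.

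With the replicate block, which takes the replicate number as a paired unit, the counts were 892, 922, 41, 5 and 354 probe sets and 11, 20, 16, 10 and 16 lists. Arrays with equal numbers were not alike, since residuals of any pair of groups had correlations of -0.147 to 0.162 and 4 of 24 arrays fitted best with their own number. Signal over background limits weakly expressed genes, whose changes the added 7.21 shrinks.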

Other observations

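The gene groups described first were chosen after the results were seen, and the relations between animals were set out before theirs. Some lists held genes that moved both ways and were not called by camera. Of 18 vasoactive and natriuretic genes, 2 rose and 4 fell at 2 weeks, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.0952, and mixed fry adjusted p = 2.89e-12). The arachidonic acid epoxygenase Cyp2c23 fell by 0.55 ± 0.08 and the hydroxylase Cyp4a3 by 0.43 ± 0.08, while the vasopressin receptor Avpr2 had 0.54 ± 0.13, with -0.33 for its other probe set. At 8 weeks 1 of the list rose and 3 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.319), and the natriuretic peptide receptor Npr1 rose by 1.09 ± 0.26. Of 27 sodium transport genes, 4 rose and 5 fell at 2 weeks, the same counts adjusted over the list alone (camera adjusted p = 0.541, mixed fry adjusted p = 8.77e-16), and 2 rose and 3 fell at 8 weeks, or 3 and 3 (camera adjusted p = 0.534, mixed fry adjusted p = 5.47e-13). The sodium bicarbonate cotransporter Slc4a4 fell by 0.47 ± 0.07 at 2 weeks and by 0.47 ± 0.07 at 8 weeks, and its other probe set had -0.97 and -0.30, the latter not called. Slc9a3, the proximal sodium proton exchanger, had 0.18 ± 0.08 at 2 weeks (adjusted p = 0.192) and -0.50 ± 0.08 at 8 weeks, and the adducin gene Add3 fell by 0.32 ± 0.06 at 8 weeks, with an uncalled -0.19 for its other probe set.

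Vitamin D and phosphate genes at 2 weeks, 16 in number, held 1 that rose and 3 that fell, also adjusted over the list alone (camera adjusted p = 0.364, mixed fry adjusted p = 3.14e-05). The vitamin D receptor Vdr fell by 0.81 ± 0.14 and the phosphate transporter Slc34a1 by 0.38 ± 0.08 (an uncalled -0.26 for its other probe set), while Slc20a1 rose by 0.50 ± 0.11. Of 15 cholesterol synthesis genes 2 rose and 3 fell at 2 weeks, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.657, mixed fry adjusted p = 3.24e-08), with Idi1 at 0.62 ± 0.14 and Sc5d at -0.42 ± 0.10, and an uncalled 0.12 and -0.07 for their other probe sets. Of 28 NRF2 targets 7 rose and 0 fell at 8 weeks, and the same adjusted over the list alone (camera adjusted p = 0.534, mixed fry adjusted p = 4.96e-08). Besides Hmox1, glutathione peroxidase Gpx2 rose by 0.84 ± 0.17 and Gstp1 by 0.38 ± 0.08. Further lists were called at neither time, with camera adjusted p = 0.578 at 2 weeks and 0.0685 at 8 weeks for podocyte, and 0.443 and 0.768 for endothelium. These values were 0.553 and 0.704 for the circadian clock, 0.942 and 0.904 for intercalated cells, and 0.782 and 0.554 for p53 targets.

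The 6 animals given the high salt and fat diet for 8 weeks had tubular injury scores of 0.817, -0.944, 0.294, -0.406, 0.930 and -0.691, and the relation of this score to 6 other list scores, without shared genes, was tested across these animals with exact permutation tests. Extracellular matrix scores rose with injury (Pearson r = 0.909, exact p = 0.0153, adjusted p = 0.0458; Spearman rho = 0.943, exact p = 0.0167, adjusted p = 0.050), with r = 0.806 without the 2 animals farthest from the median. Proximal tubule scores fell with it (r = -0.884, exact p = 0.0153, adjusted p = 0.0458; rho = -0.943, exact p = 0.0167, adjusted p = 0.050), with r = -0.931 without those animals. Interferon response had r = 0.747 (exact p = 0.0819, adjusted p = 0.164) and rho = 0.714 (exact p = 0.136), with r = 0.551 without them. Macrophage had r = 0.652 (exact p = 0.167, adjusted p = 0.232) and rho = 0.60 (exact p = 0.242), and antigen presentation r = 0.589 (exact p = 0.193, adjusted p = 0.232) and rho = 0.714 (exact p = 0.136). Without the 2 farthest animals these became -0.376 and -0.157, where 4 animals over a narrower range of scores decide little. Heat shock had r = -0.243 (exact p = 0.663) and rho = -0.257 (exact p = 0.658), with r = 0.413 without them, and 6 animals are too few to exclude a relation. As a hypothesis, animals may differ in how far injury, matrix gain and loss of proximal tubule transcripts have gone together (r = 0.909 and -0.884).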
